A study of Rattus norvegicus with 6 samples.

How the data were processed

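RNA was sequenced from whole lung of 12-week-old female rats, 3 per genotype and 6 in all. In the rats called ND1_cKO here, Cre recombinase driven by the promoter of Sftpc, the surfactant protein C gene of alveolar type 2 cells, switched on a DdCBE against ND1. A DdCBE is a protein that is targeted to a chosen site of the mitochondrial genome and converts C to T there without cutting the DNA. ND1 encodes a core subunit of respiratory complex I. The controls were littermates that carried the silent editor allele per the series description, while the sample labels call them wild type; they are called control here. Each library is a separate animal per the series description.

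The deposited table holds whole-number read counts per gene symbol, 1 column per library, and each column was assigned to its sample by the column name that the sample's description gives. No column was left without a sample (0). Per the submitters' processing notes, fastp, HISAT2, HTSeq, DESeq2 and R 4.3.3 were used, with no role or order stated. The genome build, the gene annotation and the strand setting of the counting are not given in the sources used here. Without strand, reads of overlapping or antisense genes cannot be told apart, and genes with near-identical relatives may share reads. That applies to the muscle actins, the metallothioneins, the RT1 histocompatibility genes, the haemoglobin genes, and the overlapping ATP8/ATP6 and ND4L/ND4 pairs, whose values are uncertain. Counts do not show the edit itself, so ND1 counts report transcript abundance only. The table holds 22835 genes, each with at least 1 count over all libraries. Its mitochondrial genes are 13 protein-coding ones.

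Total counts were 38303274, 35987889 and 28669995 in control replicates 1, 2 and 3. They were 36986040, 37093879 and 36526203 in ND1_cKO replicates 1, 2 and 3. No 2 libraries agreed within sampling noise: the chi-square per degree of freedom, over genes with at least 20 counts in the pair, was 23.7 or more in every pair. The biological coefficient of variation was 0.22.

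From the counts, genes were tested with the quasi-likelihood F test of edgeR 4.0.16 (robust, two-sided) in R 4.3.3, with TMM normalisation, genes kept by filterByExpr (16548 genes), genotype as the only factor and Benjamini-Hochberg adjustment. A gene was called at adjusted p below 0.05, and the study's own threshold adds an absolute log2 fold change above 1. Fold changes are ND1_cKO over control; standard errors are the absolute log2 fold change over the square root of F. Levels are normalised counts (CPM, relative to library size with TMM factors), given as mean ± SD.

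Before the data were examined, 36 gene lists were fixed, with 706 entries of which 698 were found in the table. The 35 lists with at least 5 tested genes were compared with all other genes by camera of limma 3.58.1 on voom values, with a preset correlation of 0.01, two-sided and adjusted over the lists. Camera was repeated with a correlation estimated per list, and beside it fry was run, which asks only whether the genes of a list move on balance in a direction. Counts of list members past the threshold are given over all genes tested and adjusted over the list alone. List scores are mean log2 CPM (prior count 2) relative to the control mean. The share of counts from mitochondrial genes was compared by an exact permutation test, which with 3 against 3 cannot go below p = 0.1.

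The rule for named genes was also fixed before the data were examined. It takes the mitochondrially encoded genes and Sftpc, the 8 highest and 8 lowest fold changes among called genes with a mean of at least 1 CPM and no overlap between genotypes, the 3 members with the lowest adjusted p in each list tied to the study's question, and the 2 lowest in each other list past the set test. The question lists were mitochondrially encoded genes, nuclear complex I, alveolar type 2, type 1 and transitional cells, the integrated stress response, fibrotic matrix, and myofibroblast and smooth muscle. Symbols that are only locus identifiers were passed over. Other genes named in the text were chosen after their values were seen, and each paragraph that names them says so.

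Both steps were tested on simulated data for this comparison with 16548 genes. The edgeR fit recovered 56 of 100 genes changed 2-fold and 94 of 100 changed 4-fold, with 1.96% false calls. Genes were drawn independently, with a dispersion set by their mean level and no outlying library, so the real libraries may do worse. Camera called 0 of 35 lists in unchanged data simulated without correlation between genes, so that test does not cover correlated genes. In 6 of 10 splits of the real libraries into 3 and 3, the real split included, camera called at least 17 lists. Every other split mixes the genotypes unevenly and so keeps part of the genotype difference, which camera can call. With a correlation estimated per list, camera called 0 lists in the real split. For a list, rose and fell therefore give the direction of its camera call, and the call by itself does not show an effect of genotype.

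Alternatives were DESeq2 size factors, total counts only, no filter, a minimum of 1 CPM in 3 libraries, the replicate number as a block, limma-voom, DESeq2 1.42.0, adjusted p below 0.01, an estimated correlation, fry, another denominator for the mitochondrial share, and each library left out in turn. Limma-voom with library weights was chosen after seeing the data.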

Results

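Lung RNA from 3 control and 3 ND1_cKO female rats, 12 weeks old, was compared. In ND1_cKO, Cre driven by the Sftpc promoter switched on an editor against mitochondrial ND1, which was silent or absent in controls. Cre and the active editor therefore differ between the genotypes together with the ND1 edit. Their effects cannot be told apart from that of the edit in this design. The study names the ND1_cKO rat as a model of pulmonary fibrosis. Between 28669995 and 38303274 counts were assigned to genes per library, and between 19817 and 20457 genes were detected. The first principal component held 46.6% of the variance and separated the genotypes, with controls between -38.3 and -31.1 and ND1_cKO replicates 1, 2 and 3 at 25.3, 13.7 and 65.2. ND1_cKO replicate 3 therefore stood farthest from the controls.

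ND1, the targeted gene, gave 2679, 2433 and 3083 CPM in control replicates 1 to 3 and 3679, 3427 and 3737 CPM in ND1_cKO replicates 1 to 3. Its transcript was 1.32-fold higher (log2 fold change 0.40 ± 0.12 SE, n = 3 rats per genotype) with an edgeR adjusted p of 0.125, so it did not pass the test. DESeq2 called ND1 (adjusted p = 0.0144), the only 1 of 14 alternatives in which it passed. Among the 13 mitochondrially encoded genes, COX3, a subunit of cytochrome c oxidase, rose 1.57-fold (log2 0.65 ± 0.11, adjusted p = 0.0391). COX1 was 0.63 ± 0.12 higher on the log2 scale at adjusted p = 0.0505 and COX2 0.54 ± 0.13 at 0.0806. Log2 fold changes were positive for 12 of the 13, the exception being ND4L at -0.07. ND4, at 0.01, was negative with total counts as the only scaling and without control replicate 1 or 2 or ND1_cKO replicate 1 or 3, and ND6 without control replicate 1. ND5 (0.38), CYTB (0.38), ATP6 (0.40), ND3 (0.29), ND6 (0.29), ATP8 (0.19) and ND2 (0.12) lay between them and did not pass. The list rose as a whole (camera adjusted p = 2.87e-05; adjusted p = 0.559 with an estimated correlation). It had 1 member past the threshold over all genes and 7 adjusted over the list alone. DESeq2 called 7 of the 13. With a library left out the edgeR count was 0, except 1 without ND1_cKO replicate 3. Mitochondrially encoded genes took 4.02% ± 0.23 of counts in controls and 5.45% ± 0.28 in ND1_cKO (SD, n = 3), a difference of 1.43 points with an exact two-sided permutation p of 0.1, the smallest this design allows. As counts of whole lung, the ND1 level and the mitochondrial share are not those of the targeted cells alone. The cells behind the differences were not identified.

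**Figure D1:**
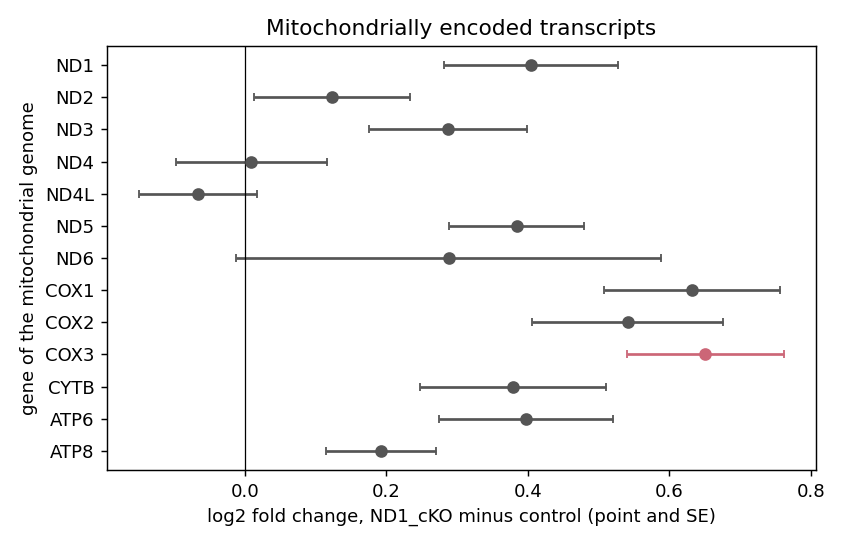
Log2 fold change (ND1_cKO minus control, x axis) of each gene of the mitochondrial genome (y axis), with its standard error as the bar, n = 3 per genotype; the red point passed adjusted p below 0.05. COX3 lies at 0.65 and ND4L at -0.07.

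Across the lung, 400 of 16548 genes differed between genotypes, 188 higher and 212 lower in ND1_cKO, and 163 also passed the study's fold threshold (111 higher, 52 lower). Acta1, skeletal muscle alpha-actin, had the largest rise among the genes the naming rule admits, from 1.48 ± 0.82 to 155 ± 79.7 CPM (log2 6.67 ± 0.62, adjusted p = 0.0162). Its reads can be shared with other actins. By the same rule the other leading rises were A2m (5.12 ± 0.79), the fibrillar collagen gene Col11a1 (4.97 ± 0.81), Tmem213 (4.54 ± 0.73), Car12 (4.42 ± 0.75), the gap junction gene Gjb6 (4.28 ± 0.48), the cytokine gene Il24 (4.24 ± 0.73) and Ptprn (3.97 ± 0.72). The leading falls were Nkx2-8 (-6.21 ± 0.82), Baat (-4.70 ± 0.38), Phf11b (-4.01 ± 0.40), Serpinb10 (-3.98 ± 0.39), Asb15 (-3.22 ± 0.48), Acoxl (-3.13 ± 0.34), Vil1, which encodes the microvillar protein villin (-3.09 ± 0.31), and Sh2d7 (-3.06 ± 0.50). In all 400 genes every library of a genotype lay above every library of the other. For called genes that nearly follows from a small p with 3 libraries per genotype. Over all genes tested it held for 28.2%, against 10% by chance. The number of calls was 0 without control replicate 2, 9 without control replicate 3, 23 without ND1_cKO replicate 1 and 184 without control replicate 1, and 0, 3, 4 and 16 of the 33 named genes that passed still passed in these fits. DESeq2 called 1879 genes, all 400 among them with the same sign.

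Genes used as markers of the alveolar transitional state, between type 2 and type 1 cells, rose in these whole-lung libraries, which do not show the cell of origin. Krt19 is also on the mesothelial list, and the mesothelial and basal lists had medians of 0.81 and 0.85 without passing. Of 23 tested, 8 rose and 0 fell (15 and 0 adjusted over the list alone), with a median log2 fold change of 0.69 (camera adjusted p = 1.14e-09; adjusted p = 0.371 with an estimated correlation). Krt7, a keratin of simple epithelium, rose 1.82-fold (log2 0.86 ± 0.09, adjusted p = 0.0162), Krt19 1.62-fold (0.70 ± 0.10, adjusted p = 0.0295) and Areg, the EGF receptor ligand amphiregulin, 6.39-fold (2.68 ± 0.37, adjusted p = 0.0295). The remaining 5, listed after their values were seen, were Krt8, F3, Krt17, Plaur and Fosl1, with Krt17 moving from 0.264 ± 0.159 to 3.46 ± 1.92 CPM. The count of 8 was 13 with DESeq2, 5 with limma-voom, 3 without control replicate 1 and 0 without control replicate 2 or 3 or ND1_cKO replicate 1. The type 2 list went both ways and did not pass as a list (median 0.10, camera adjusted p = 0.575). In it the cathepsin gene Ctsh (0.78 ± 0.12, adjusted p = 0.0311) and the surfactant protein gene Sftpd (0.81 ± 0.12, adjusted p = 0.0317) rose, as 2 of 15 over all genes against 5 higher and 3 lower adjusted over the list alone. Etv5, a transcription factor of type 2 cells, was at -0.98 ± 0.20 (adjusted p = 0.0539), and Sftpc, whose promoter drives the Cre, had 14010 ± 1322 CPM in controls and 8162 ± 2599 in ND1_cKO (-0.78 ± 0.24, adjusted p = 0.133). The type 1 list fell (14 of 17 negative, median -0.24, camera adjusted p = 0.00214, and 0.559 with an estimated correlation). Of its 17 genes 0 passed over all genes and 0 adjusted over the list alone, and Spock2 (-1.42 ± 0.31), Clic5 (-0.77 ± 0.20) and Rtkn2 (-1.08 ± 0.34) had the lowest p-values. Its score was -0.795 in ND1_cKO replicate 3 against -0.308 and -0.144 in the other ND1_cKO libraries and -0.178 in control replicate 1, so the genotypes overlapped. Its median was -0.40 without ND1_cKO replicate 2 and -0.14 without ND1_cKO replicate 3. DESeq2 called 4 of the type 1 genes, all lower, and 5 higher and 3 lower in the type 2 list. With edgeR 0 of the type 2 list passed without control replicate 1, 2 or 3 or ND1_cKO replicate 1, and 5 higher and 1 lower passed without ND1_cKO replicate 3.

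Genes of the fibrotic matrix had positive log2 fold changes in 41 of 41 tested, with a median of 1.13, a 2.19-fold difference (camera adjusted p = 1.52e-11; adjusted p = 0.559 with an estimated correlation). Of the 41, edgeR with all 6 libraries called Col16a1 alone over all genes, a collagen of the fibril-associated kind (2.74-fold, log2 1.46 ± 0.11, adjusted p = 0.0119), against 14 adjusted over the list alone. Counted over all 42 listed genes, of which each fit tests those its filter keeps, the 1 was 19 with DESeq2 (18 among the 41), 4 with library weights, 2 without a filter, 0 without control replicate 2, 11 without ND1_cKO replicate 2 and 5 without ND1_cKO replicate 3. Col6a3 was at 0.66 ± 0.14 (adjusted p = 0.0632) and Fn1, which encodes fibronectin, at 1.85 ± 0.40 (adjusted p = 0.0664). Col1a1, named after its values were seen, stood at 227 ± 36.7 CPM in controls and 1354 ± 956 in ND1_cKO (2.58 ± 0.58, adjusted p = 0.0751). The smallest of the 41 log2 fold changes, also named after seeing them, were those of Postn (0.005), Comp (0.08) and Dcn (0.12). With DESeq2 Postn was at -0.003, so the sign of that gene depends on the method. The list score was 1.03, 0.399 and 1.94 in ND1_cKO replicates 1, 2 and 3, and without replicate 3 the median was 0.69. Myofibroblast and smooth muscle genes did not pass (0 of 15 over all genes and 0 adjusted over the list alone). Their median of 0.09 (between -0.44 and 0.31 with a library left out) and mean of 0.13 differed in sign from the set test, which pointed down (adjusted p = 0.665). Without ND1_cKO replicate 3 the list passed as lower (median -0.44, adjusted p = 0.000289). In that list Mylk (-0.35 ± 0.11), Aspn (1.28 ± 0.43) and Myh11 (-0.34 ± 0.21) had the lowest p-values. The TGF-beta list did not pass (median 0.22, adjusted p = 0.13), and its median was 0.03 without ND1_cKO replicate 3, yet of its 24 genes 2 rose and 1 fell, against 4 and 1 adjusted over the list alone. These, named after their values were seen, were the ligand gene Tgfb2 (1.02 ± 0.11, adjusted p = 0.0162) and the integrin gene Itgb8 (0.94 ± 0.14, adjusted p = 0.0302), both higher, and the inhibitory Smad6 (-0.87 ± 0.08, adjusted p = 0.0154), lower. Smad7 (-0.29) and Tgfb1 (-0.03), also named after their values were seen, did not pass. Smad6 fell in libraries in which the endothelial list also fell (median -0.65), so its fall is not assigned to TGF-beta signalling. Of the TGF-beta list 0 passed without control replicate 2 or ND1_cKO replicate 1, 1 higher and 1 lower without control replicate 1, and 1 higher without control replicate 3. Alveolar fibroblast genes fell (10 of 14 negative, median -0.38, camera adjusted p = 0.0392, and 0.559 with an estimated correlation). In the list 1 of 14 fell over all genes and 3 adjusted over the list alone, with Limch1 at -0.71 ± 0.13 (adjusted p = 0.0411) and Plin2 at -0.47 ± 0.11 (adjusted p = 0.0657). The count of 1 was 0 without control replicate 1, 2 or 3 or ND1_cKO replicate 1, while DESeq2 called 4 lower and 1 higher. The set test of the alveolar fibroblast list did not pass without control replicate 3 (adjusted p = 0.104), without ND1_cKO replicate 2 (0.0657), with total counts only (0.0615) and with the 1 CPM minimum (0.0532).

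**Figure D2:**
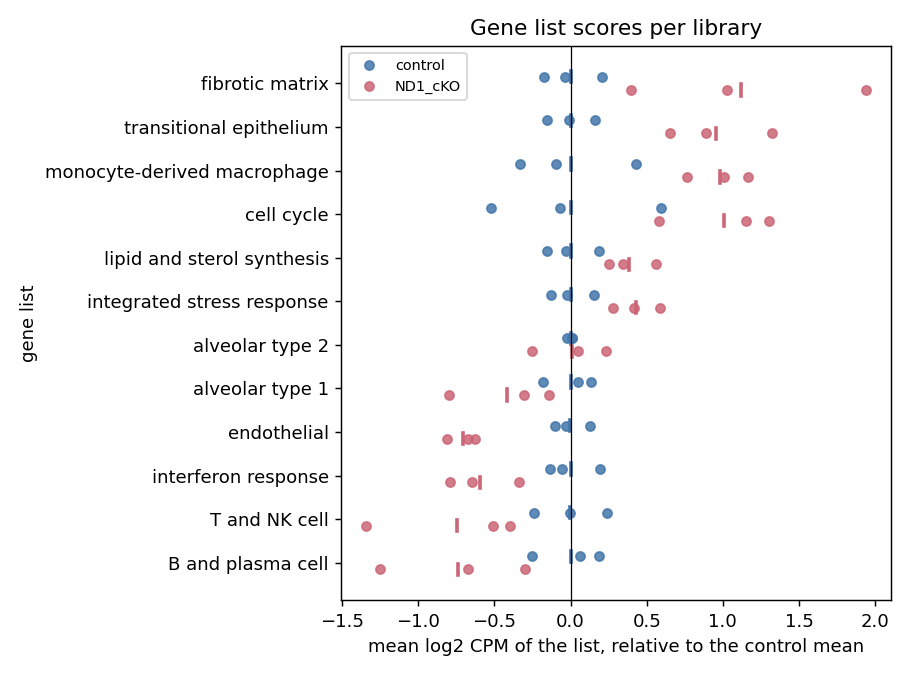
Score of 12 gene lists (y axis), the mean log2 CPM of the list relative to the control mean (x axis), with a point per library and a bar at the mean of each genotype, n = 3. ND1_cKO replicate 3 lies at 1.94 for fibrotic matrix, and the endothelial scores of ND1_cKO lie between -0.813 and -0.628.

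Among metabolic and stress programmes, nuclear genes of complex I (34 of 36 positive, median 0.17, camera adjusted p = 3.52e-06) and of the other respiratory complexes (38 of 38 positive, median 0.25, camera adjusted p = 3.78e-09) rose by small amounts. Both calls were lost with an estimated correlation, at adjusted p = 0.559 for each. In complex I 0 genes passed over all genes and 0 adjusted over the list alone, with Ndufb2 at 0.55 ± 0.14, Ndufb6 at 0.38 ± 0.11 and Ndufa1 at 0.44 ± 0.13. In the other complexes Cox8a passed (0.55 ± 0.11, adjusted p = 0.0495), 1 gene by either adjustment, while Uqcr10 was at 0.40 ± 0.10. In that list 0 passed with DESeq2 size factors, total counts only or limma-voom, 2 passed with DESeq2, and with a library left out 0 passed except 1 without ND1_cKO replicate 3. Complex I scores overlapped, with control replicate 1 at 0.145 and ND1_cKO replicate 3 at 0.14. The complex I median was 0.26 without control replicate 1, and that of the other complexes 0.17 without control replicate 2. Glycolysis rose (median 0.36, camera adjusted p = 3.96e-05; adjusted p = 0.559 with an estimated correlation). Of its genes 0 of 20 passed over all genes and 9 adjusted over the list alone, and Tpi1 was at 0.54 ± 0.12 and the lactate transporter gene Slc16a3 at 1.27 ± 0.30. Scores of that list overlapped too, with control replicate 1 at 0.283 and ND1_cKO replicate 2 at 0.281. Lipid and sterol synthesis rose (24 of 28 positive, median 0.43, camera adjusted p = 2.37e-06, and 0.559 with an estimated correlation). Over all genes 3 of 28 rose, and 9 adjusted over the list alone, among them Chka (0.47 ± 0.07, adjusted p = 0.0351) and Idi1 (0.96 ± 0.17, adjusted p = 0.0418). Its median was 0.26 without ND1_cKO replicate 2. The integrated stress response, the programme that limits translation and induces amino acid synthesis, rose as a list (28 of 36 positive, median 0.30). Its camera adjusted p was 0.000185, and 0.559 with an estimated correlation. Of its 36 genes 0 passed over all genes and 5 adjusted over the list alone, and the leading members were Aldh1l2 (3.12 ± 0.63), the cystine transporter gene Slc7a11 (2.41 ± 0.50) and Pck2 (0.48 ± 0.11). Other members, named after their values were seen, differed less, such as Atf4 (0.20), Asns (0.22) and Ddit3 (-0.01). The median of the list was 0.48 without control replicate 1, and 3 of its genes passed over all genes without ND1_cKO replicate 2, without ND1_cKO replicate 3 and with library weights. Cell cycle genes were positive in 30 of 30 and rose as a list (median 1.15, camera adjusted p = 1.92e-10; adjusted p = 0.559 with an estimated correlation). Over all genes 0 passed, and 15 adjusted over the list alone, with Foxm1 at 0.79 ± 0.17 and Birc5 at 1.44 ± 0.34. Control replicate 1 scored 0.594 on that list, above the 0.58 of ND1_cKO replicate 3. DESeq2 called 17 cell cycle, 10 lipid and sterol, 8 integrated stress response, 6 glycolysis and 2 complex I genes, all higher, and library weights 13 cell cycle genes. The 3 lipid and sterol genes were 0 without control replicate 2 or 3 or ND1_cKO replicate 1, 2 without control replicate 1 and 1 without ND1_cKO replicate 2 or 3. Mitochondrial protein quality control (median 0.10, adjusted p = 0.0525; 0 of 17 genes by either adjustment) and p53 and senescence genes (median 0.20, adjusted p = 0.0529) did not pass. In the latter Plk2, named after its value was seen, fell (-0.62 ± 0.09) as 1 of 19 genes, against 7 higher and 2 lower adjusted over the list alone. For p53 and senescence genes the count lower was 0 without control replicate 1, 2 or 3 or ND1_cKO replicate 1 or 2. In the last of these 1 was higher, and DESeq2 called 5 higher and 1 lower. The cells from which the transcripts of these metabolic and stress lists came cannot be seen in whole-lung libraries.

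Endothelial markers fell. Of 20 tested, 8 fell and 0 rose (15 and 0 adjusted over the list alone), with a median of -0.65 (camera adjusted p = 1.24e-11; adjusted p = 0.333 with an estimated correlation). Ptprb, a receptor phosphatase of vascular endothelium, went from 968 ± 60.8 to 521 ± 55.8 CPM (-0.89 ± 0.11, adjusted p = 0.019), and the VEGF receptor gene Flt1 from 329 ± 31.9 to 209 ± 4.82 CPM (-0.66 ± 0.09, adjusted p = 0.0292). The list score was -0.628, -0.674 and -0.813 in the ND1_cKO libraries. Lymphatic endothelial genes did not pass (0 of 7 by either adjustment, median 0.31, adjusted p = 0.969), and their median was -0.07 without ND1_cKO replicate 3. Interferon response genes were negative in 31 of 31 and fell (median -0.60, camera adjusted p = 1.33e-15; adjusted p = 0.371 with an estimated correlation), with 6 lower over all genes and 24 adjusted over the list alone. Xaf1 (-0.83 ± 0.12, adjusted p = 0.0291) and Herc6 (-0.83 ± 0.13, adjusted p = 0.032) led them. DESeq2 called 14 endothelial and 23 interferon genes. The edgeR counts of 8 endothelial and 6 interferon genes were both 0 without control replicate 2 or 3 or ND1_cKO replicate 1. Without control replicate 1 they were 3 and 0.

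**Figure D3:**
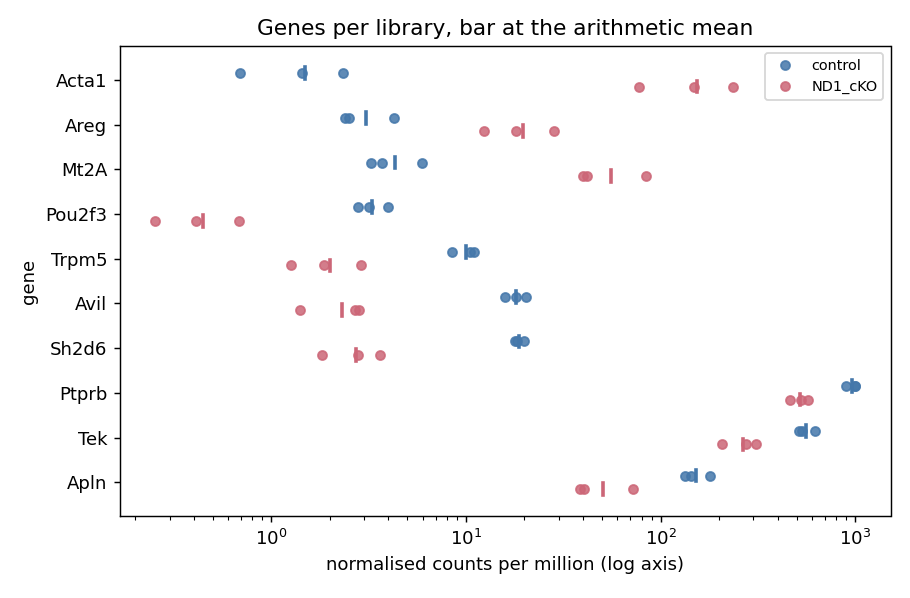
Normalised CPM (x axis, log scale) of 10 genes (y axis), with a point per library and a bar at the arithmetic mean of each genotype, n = 3. Acta1 lies between 0.688 and 2.33 CPM in controls and between 77.9 and 237 CPM in ND1_cKO.

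Of the immune cell lists, genes of monocyte-derived macrophages rose (20 of 23 positive, median 0.91, camera adjusted p = 3.01e-07; adjusted p = 0.559 with an estimated correlation). In that list 4 rose over all genes, while adjusted over the list alone 14 were higher and 1 lower. Pf4 rose 2.69-fold (1.43 ± 0.15, adjusted p = 0.0162) and the lysosomal protease gene Ctsb 1.72-fold (0.78 ± 0.11, adjusted p = 0.0304). The others, named after their values were seen, were Cd63 and Arg1. Whole-lung libraries do not show which cells the transcripts of this or the other immune lists came from. The count of 4 was 13 with DESeq2, 8 with library weights, 0 without control replicate 2 or 3, 1 without ND1_cKO replicate 1 and 2 without ND1_cKO replicate 3. T and NK cell genes fell (21 of 24 negative, median -0.76, camera adjusted p = 2.77e-08, and 0.559 with an estimated correlation). Over all genes 0 of 24 passed, and 10 were lower adjusted over the list alone, with Cd2 at -0.68 ± 0.13 (adjusted p = 0.0505) and Cd3g at -0.66 ± 0.15. B and plasma cell genes were negative in 17 of 17 and fell (median -0.73, camera adjusted p = 7.16e-07; adjusted p = 0.559 with an estimated correlation). In the list 0 passed over all genes and 7 adjusted over the list alone, with Ms4a1 at -0.91 ± 0.25 and Cd22 at -0.73 ± 0.22. MHC class II genes fell (8 of 10 negative, median -0.41, camera adjusted p = 0.00582, and 0.559 with an estimated correlation). By either adjustment 0 of 10 passed, with RT1-Ba at -0.46 ± 0.13 and RT1-DOa at -0.76 ± 0.23, both of a family that can share reads. The set test of the MHC class II list did not pass without control replicate 1 (adjusted p = 0.118), and the median of that list was -0.26 without ND1_cKO replicate 3. DESeq2 called 11 T and NK, 8 B and plasma and 2 MHC class II genes, all lower. T and NK scores were -0.397, -0.507 and -1.34 and B and plasma scores -0.297, -0.671 and -1.25 in ND1_cKO replicates 1, 2 and 3.

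The lists of other cells and of handling did not pass. Medians were 0.08 for alveolar macrophages (adjusted p = 0.45), 0.35 for neutrophils (0.185), 0.70 for mast cells and eosinophils (0.0758), 0.32 for club and goblet cells (0.129) and 0.18 for ciliated cells (0.142). They were 0.85 for basal cells (0.321), 0.81 for mesothelium (0.0813), -0.03 for erythroid genes (0.49) and -2.15 for heart muscle (0.142). They were -0.10 for adipocytes (0.332), 0.14 for cytokines and chemokines (0.515) and 0.39 for immediate early genes (0.154). Several of these calls, and those of the lists named above that did not pass, depended on the setting or on a single library. Mast cells and eosinophils (adjusted p = 0.0399) and p53 genes (0.0451) passed as higher with total counts only. Without a filter, p53 genes (0.0354) and mitochondrial protein quality control (0.0468) passed as higher and heart muscle as lower (0.0127). Without control replicate 1, mitochondrial protein quality control (adjusted p = 0.0111), mast cells and eosinophils (0.0461) and club and goblet cells (0.0449) passed as higher. Without control replicate 2 this held for neutrophils (0.0402) and ciliated cells (3.29e-05). Without control replicate 3 p53 genes (0.0275) and mesothelium (0.00975) passed as higher and heart muscle as lower (5.58e-05). Without ND1_cKO replicate 1 p53 genes (0.0312), mast cells and eosinophils (0.0447) and mesothelium (0.0258) passed as higher. Without ND1_cKO replicate 2 this held for TGF-beta (0.0324), p53 genes (0.0229), mast cells and eosinophils (0.015), mesothelium (0.0229) and immediate early genes (0.00574), and without ND1_cKO replicate 3 for mitochondrial protein quality control (0.00707) and mast cells and eosinophils (0.00557). With a library left out the median took the opposite sign for several lists that did not pass. These include mesothelium without ND1_cKO replicate 3 (-0.50), alveolar macrophages without control replicate 3 (-0.08) or ND1_cKO replicate 1 (-0.12), type 2 cells without ND1_cKO replicate 2 (-0.12), adipocytes without control replicate 1 (0.05) and erythroid genes without ND1_cKO replicate 2 (0.13). Without ND1_cKO replicate 3 the medians of immediate early genes and neutrophils were 0.03 and 0.07, and without control replicate 1 that of heart muscle was -0.49. Without control replicate 1 the medians of mast cells and eosinophils, club and goblet cells and mesothelium were 1.40, 0.61 and 0.49. Those of neutrophils, ciliated cells and club and goblet cells were 0.56, 0.43 and 0.16 without control replicate 2. Without control replicate 3 the medians of mesothelium, ciliated cells and club and goblet cells were 1.68, 0.06 and 0.21, and basal cells had 0.57 without ND1_cKO replicate 3. The erythroid mean was 0.03, opposite in sign to its median and test. Adjusted over the list alone, 6 mast cell and eosinophil genes were higher and 1 lower, 2 alveolar macrophage genes were higher, and 1 adipocyte gene was lower. Cytokines had 1 higher and 1 lower, mesothelium 1 higher and ciliated cells 1 lower, while neutrophil, club and goblet, basal, erythroid, heart muscle and immediate early genes had 0. Mast cell and eosinophil genes had 0 over all genes, but 6 higher and 1 lower with DESeq2. With edgeR they had 4 higher without ND1_cKO replicate 3 and 2 higher without ND1_cKO replicate 2. Over all genes, the members that passed, named after their values were seen, were Atp6v0d2 among alveolar macrophage genes (3.73 ± 0.35), the alarmin gene Il33 among cytokines (-1.02 ± 0.11), Krt19 among mesothelial genes and Tppp3 among ciliated genes (-0.80 ± 0.10). Heart muscle scores ranged from -2.40 to 2.10 between control libraries, and mesothelial scores were 1.03 in control replicate 3 and 2.10 in ND1_cKO replicate 3. The thymus list, with 2 genes tested, was too short for the set test and had a median of -0.44, with 0 past by either adjustment.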

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

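Limma-voom with library weights was chosen after seeing the data; the other alternatives given here were fixed before. The count of 400 genes was 404 with DESeq2 size factors, 455 with total counts only (183 higher, 272 lower), 524 without a filter, 421 with the 1 CPM minimum and 376 with limma-voom. It moved to 1879 with DESeq2, 950 with library weights and 0 at adjusted p below 0.01 (lowest 0.0119; 3533 genes at unadjusted p below 0.05). Leaving out each library in turn gave 0 to 495 genes, the 0 without control replicate 2 standing beside 2609 genes at unadjusted p below 0.05. The cause of the shifts with DESeq2, with library weights and with single libraries was not tested. The 163 genes past the study's fold threshold became 651 with DESeq2, 321 with library weights and 0 to 203 with a library left out. All 400 genes kept their sign in each alternative that tested them (383 were tested with the 1 CPM minimum). Their levels did not overlap between the genotypes, so a kept sign was close to given and is no further support. Of the gene lists, 17 passed, 16 to 20 under the other scalings and filters and 19 to 21 with a library left out, but 0 with an estimated correlation (lowest adjusted p 0.333) and 3 with fry. These 3 were endothelial (fry adjusted p = 0.017), interferon response (0.0449) and alveolar transitional genes (0.0449). The mitochondrial share differed by 1.43 points, 1.51 with another denominator and 1.29 to 1.57 with a library left out; summing all mitochondrial features equals summing the 13 protein-coding genes here. Limma-voom is already the basis of the set test, so that alternative adds nothing for lists. With the replicate number as a block, 262 genes (173 of them among the 400), 140 past the fold threshold and 22 lists passed. The block ended the call of alveolar fibroblast genes (adjusted p = 0.0733). It moved counts of called members from 1 to 8 in fibrotic matrix and 0 to 2 in the integrated stress response and in mast cells and eosinophils, but from 8 to 2 in endothelium, 8 to 4 in transitional genes, 6 to 3 in interferon, 4 to 2 in monocyte-derived macrophages, 3 to 1 in lipid and sterol synthesis and 1 to 0 in mitochondrially encoded and other respiratory complex genes. It brought past TGF-beta (0.0483), mitochondrial protein quality control (0.0422), p53 genes (0.0229), mast cells and eosinophils (0.00409) and mesothelium (0.000613) as higher, and heart muscle (0.00343) as lower. Same-numbered libraries correlated in their deviations at 0.165, 0.0235 and 0.135, not all above 0.1, so the numbers are not taken to pair the samples, although every library correlated best with its own number, a hint from the data and not from the design. Of the 33 named genes that passed, between 25 and 33 also passed in the alternatives other than leaving out a library, the stricter threshold apart. No called gene or list reversed, which for the genes was close to given by their selection. With 3 libraries per genotype, 56 of 100 simulated 2-fold changes were recovered in data without an outlying library, which limits what a missed call shows.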

Other observations

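The genes and groups in this part were chosen after their values were seen, and some of the genes also belong to the fixed lists. The metallothionein genes Mt1 and Mt2A, which bind zinc and copper, rose from 8.39 ± 3.58 to 66.4 ± 28.4 CPM (log2 2.98 ± 0.41) and from 4.32 ± 1.46 to 55.4 ± 25.1 CPM (3.67 ± 0.40), though they can share reads. Among the ligands of the EGF receptor, Areg and Ereg (2.25 ± 0.39) rose, while Hbegf (0.33), Tgfa (0.31) and Egf (-0.25) did not pass. Of 12 Notch and BMP pathway genes, many of them expressed by endothelium, 4 fell in the libraries in which the endothelial list also fell (median -0.65): Efnb2 (-0.97 ± 0.11), Smad6, Tmem100 (-1.08 ± 0.18) and the Notch ligand gene Dll4 (-1.35 ± 0.23). The other 8 did not pass: Hey1 was at -0.85 (adjusted p = 0.0936), Id3 at -0.35 and Smad7 at -0.29, and Jag1, Jag2, Hes1, Id1 and Dll1 lay between -0.09 and 0.07. The median of the 12 was -0.32, and a change apart from the endothelial fall was not tested. The macrophage gene Spp1, osteopontin, stood at 33.1 ± 23.9 CPM in controls and 451 ± 192 in ND1_cKO (3.76 ± 0.69) without passing (adjusted p = 0.0526), and so did the mast cell tryptase gene Tpsab1, 30.5-fold higher in ND1_cKO (4.93 ± 1.00, adjusted p = 0.0641).

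The tests of the 3 patterns that follow were chosen after the values they use had been seen, except that of cartilage genes and the splits of the libraries, which were fixed before their results; leaving out single libraries in them was added after seeing the data.

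Of 11 tested genes largely restricted to tuft cells, rare chemosensory epithelial cells, 8 fell, with a median log2 fold change of -2.88. Of 16 tuft cell genes that other cells also express, 2 fell, Vil1 and Sox9, and the median of the 16 was -0.44. The others ranged from -1.59 for Espn to 0.57 for Ptgs1 without passing. Pou2f3, the transcription factor that defines the cell type, lay between 2.78 and 3.98 CPM in controls and between 0.253 and 0.679 CPM in ND1_cKO, and Trpm5, Avil and Sh2d6 fell by 2.31, 2.97 and 2.77 on the log2 scale. A smaller amount of airway in the tissue pieces is argued against, since 38 secretory, ciliated and basal markers had a mean difference of 0.332 (SD 0.222), or 0.162 (SD 0.08) without control replicate 3, in place of a fall. A smaller amount of cartilage-bearing large airway stays open, as the summed cartilage genes differed by -0.392 (SD 0.248), a sum made up mostly of Cytl1 while Col2a1 was at 0.0786 CPM or less in every library. Neither test covers tuft cells outside the airway, whose share of these transcripts is not known here. Fewer tuft cells may account for the fall, but the restricted genes differed in their falls (chi-square p = 2.38e-06). That test takes the standard errors as exact and the genes as independent, so its p is approximate. Genes that are only largely restricted could also fall unequally if cell number alone changed, so the unequal falls do not decide the question. Cell number and expression per cell cannot be told apart in bulk tissue, where counts of tuft cells in sections would be the test.

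The fall of endothelial markers, to a list score of -0.705 in ND1_cKO (SD 0.097), could arise if RNA of other cells diluted all cell types evenly. Relative to 63 ciliated, secretory, smooth muscle, lymphatic and red blood cell markers, the endothelial markers were lower by a log2 difference of -0.867 (SD 0.326), which argues against a dilution that reaches those cells evenly. That set holds no list that fell past the set test, although 7 lists did, against 10 that rose. T and NK cell genes (median -0.76) and B and plasma cell genes (-0.73) fell as far as the endothelial list (-0.65). The comparison therefore cannot tell an endothelial change from a fall shared with those cells. A selective loss of capillary endothelium would lower capillary markers further than general ones: the difference was -0.423 (SD 0.321), less than 2 SD from 0. It rested on single libraries, at -0.196 (SD 0.194) without ND1_cKO replicate 3 and -0.612 (SD 0.29), more than 2 SD from 0, without ND1_cKO replicate 2. General endothelial markers also mark capillary cells, so a capillary loss would lower both sets, and their difference could miss it. A loss of capillary cells stays open, and bulk tissue does not separate cell number from expression per cell, so these cannot be told apart.

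The rise of Acta1 might come from skeletal muscle in the tissue pieces or from reads of the other muscle actins. The median of 17 other skeletal muscle genes was at most 0.577% of the Acta1 level in any ND1_cKO library, and Ckm, the muscle creatine kinase gene, was at 0.0818, 0.272 and 0.0281 CPM there, which argues against muscle tissue. Myh1 and Myh2 were at 20.7 and 10.3 CPM in ND1_cKO replicate 3 alone. The lowest ratio of Acta1 to Acta2, Actc1 and Actg2 in ND1_cKO was 26.5 times the highest in controls, which argues against a fixed share of their reads. Expression of Acta1 by lung cells of ND1_cKO rats remains as a hypothesis, which in situ hybridisation or single-cell RNA-seq of Acta1 would test.

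Of the 10 ways to split the 6 libraries into 3 and 3, only the real split (1) called any gene: 400, against at most 0 in the others, and the same split (1) gave 163 genes past the study's fold threshold against at most 0. For gene lists, 6 of the 10 splits gave as many as the 17 of the real one, with a highest of 20 in the others. For genes, 10 splits are too few for a share under 0.05, since it cannot fall below 0.1. Every other split also mixes the genotypes unevenly. A genotype difference then widens the spread within groups, which makes few gene calls likely. Part of it remains between the groups, where camera can call lists. The other splits are therefore not a reference free of genotype, for genes or for lists. Splits that mix the genotypes passed as many lists, so the number of camera calls at the preset correlation does not set the real split apart. It does not show whether genotype lies behind those calls.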
